A study of Homo sapiens with 9 samples.

How the data were processed

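Human dermal papilla spheres of 3 donors were measured on 9 arrays, 3 each for DMSO, ruxolitinib and tofacitinib. Per the labels' protocols, total RNA was amplified to cDNA before hybridisation. The deposited log2 values were made with GCRMA, which corrects the background, normalizes arrays and summarises probe sets, per the submitters' processing notes; its version is not given in the sources used here. That the scale is log2 was inferred from this method and from the range of the values. Degraded RNA can lower the signal of probe sets far from the 3' end of a transcript, and GCRMA draws dim probe sets together.

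The table held 54675 probe sets, 62 of them controls. The platform annotation gave 41097 probe sets 1 gene symbol and 1801 several, while 11777 had none here. Symbols were looked up by Entrez identifier for 41037 probe sets in a RefSeq gene table of GRCh38.p14, used for names only. Genes on the Y chromosome and XIST were left out (35 genes), and some genes of the lists were not analysed here. Each of 19740 genes was represented by its probe set with the highest mean, and the 10533 genes with a mean of at least 4 were tested. Of 38 named genes with another probe set at that level, 13 had one of opposite sign for both drugs against DMSO.

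Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, on all 9 arrays with arm and donor as fixed terms (4 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The comparisons were each drug with DMSO, the mean of both with DMSO, and tofacitinib with ruxolitinib. Donor was a block because the labels' protocols say that cells of every donor went into all arms. The pairing was checked: deviations of same-donor arrays from their arm means correlated between 0.41 and 0.80, those of other donors between -0.76 and -0.09, and 9 of 9 arrays lay closest to their own donor. For 2 arrays 1 label field gave another donor number than the title, and the title was followed.

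A total of 24 gene lists was fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. Lists with at least 5 tested members (19) were tested with camera at a preset correlation of 0.01, and the others are given as levels. List means were fitted with limma for their SE and 95% interval. Camera with an estimated correlation and fry, which tests whether genes of a set move one way on balance, were alternatives. Members are counted past the threshold over all genes and adjusted over the list alone. Named are up to 10 genes per direction past the threshold with the same sign in all donors, or, where fewer than 5 pass, the 5 with the smallest p as values (for each comparison, including tofacitinib with ruxolitinib). From each list up to 4 members past the threshold or otherwise at most 2 with the smallest p are named, and JAK1, JAK2, JAK3, TYK2, STAT3, SOCS3, VCAN and LEF1 always. ALPL, also on that list, was below the level for testing.

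Other settings were no donor block, donor as a random block, only the arms compared, median centring, quantile normalization, no filter on dim genes and a stricter filter at 6. Further settings were the mean of probe sets, every probe set, trended and robust variances, array weights, and leaving out each donor and each array. Leaving out an array of an arm not compared kept the estimates and could alter only their spread. For both drugs, leaving out a DMSO array gave the same estimates as leaving out its donor. The leave-out fits are therefore not all separate checks of a result. A fit with the ACTB difference as a covariate and the type I interferon list without IFITM1 were added after the data were seen, as was the count of lists shared by the drugs over 100 assignments of the arms within donors, drawn with a fixed seed. The steps were tested on simulated data with the measured means and spreads of 10533 genes. Of 200 genes changed, 66.4% of those changed 2-fold and 98.6% of those changed 4-fold were recovered for tofacitinib against DMSO. For ruxolitinib against DMSO these were 65.5% and 98.5%, for the drugs against each other 67.3% and 98.7%, and for both against DMSO 82.5% and 99.4%. The simulated noise was independent between genes, and 200 genes changed at once, which eases the adjusted threshold. These shares therefore do not give the power where few genes change. In the data IFITM1 itself did not pass for either drug alone in the main fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.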

Results

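Gene expression was measured on arrays in human dermal papilla cells, the mesenchymal cells at the base of the hair follicle, grown as spheres in hanging drops of 1000 cells. Cells from 3 donors were kept with the vehicle DMSO, with ruxolitinib or with tofacitinib, which are small-molecule inhibitors of the Janus kinases (JAK). Per the labels, each drug was used at 400 nM and the treatment lasted 48 h. The labels also give 24 h of aggregation and collection 48 h after plating, so the exact hours of drug exposure are not certain. Every donor gave 1 array to each of the 3 arms, so that n = 3 donors per arm and 9 arrays in all. Values are on a log2 scale, and the number of arrays limits their precision. The arrays had medians between 2.97 and 3.02, and 10533 genes with a mean of at least 4 were tested.

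The spheres expressed the dermal papilla proteoglycan gene VCAN at 12.06 ± 0.47 in DMSO (SD, n = 3) and the Wnt effector LEF1 at 6.76 ± 0.38. Of the 39 dermal papilla signature genes on the array, 24 reached the level for testing, and ALPL did not. Most markers of other cell types were dim: the median level was 2.04 for the keratinocyte list, 2.31 for melanocytes, 2.57 for endothelium, 2.30 for leukocytes and 2.76 for adipocytes. Few of their members reached the level for testing. These were KRT10, DSP, SFN and PERP (at 11.69) among keratinocyte markers, MITF (8.75) among melanocyte, PECAM1 (7.09) among endothelial, CD4 and LAPTM5 (7.32) among leukocyte and 0 among adipocyte markers. The difference of both drug arms from DMSO in the mean of these lists lay between -0.03 and 0.12. Donor accounted for 70.2% of the variance over all genes tested and treatment for 10.2%. Of the 36 ways to assign the arms within donors, 17 gave a treatment share at least as large (exact permutation p = 0.472).

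The mean of both drug arms was compared with DMSO to ask what JAK inhibition changed in these spheres. IFITM1, an interferon-induced membrane protein that restricts virus entry, fell by 2.40 on the log2 scale (SE 0.20, n = 3 donors). Its level was 9.68 ± 0.61 in DMSO, 7.28 ± 1.22 with ruxolitinib and 7.30 ± 1.07 with tofacitinib (SD, n = 3), lower with the drugs in 3 of 3 donors. Type I interferon response genes fell as a group at camera's preset correlation, and so did cell cycle genes (adjusted p = 0.0901 and adjusted p = 0.164 with an estimated correlation). Targets of p53 and senescence genes rose as a group (adjusted p = 0.35 with an estimated correlation). IFITM1 was the 1 gene of 10533 past the threshold (limma, Benjamini-Hochberg adjusted p = 0.0384), and 504 genes had an unadjusted p under 0.05 where 527 are expected by chance.

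**Figure D1:**
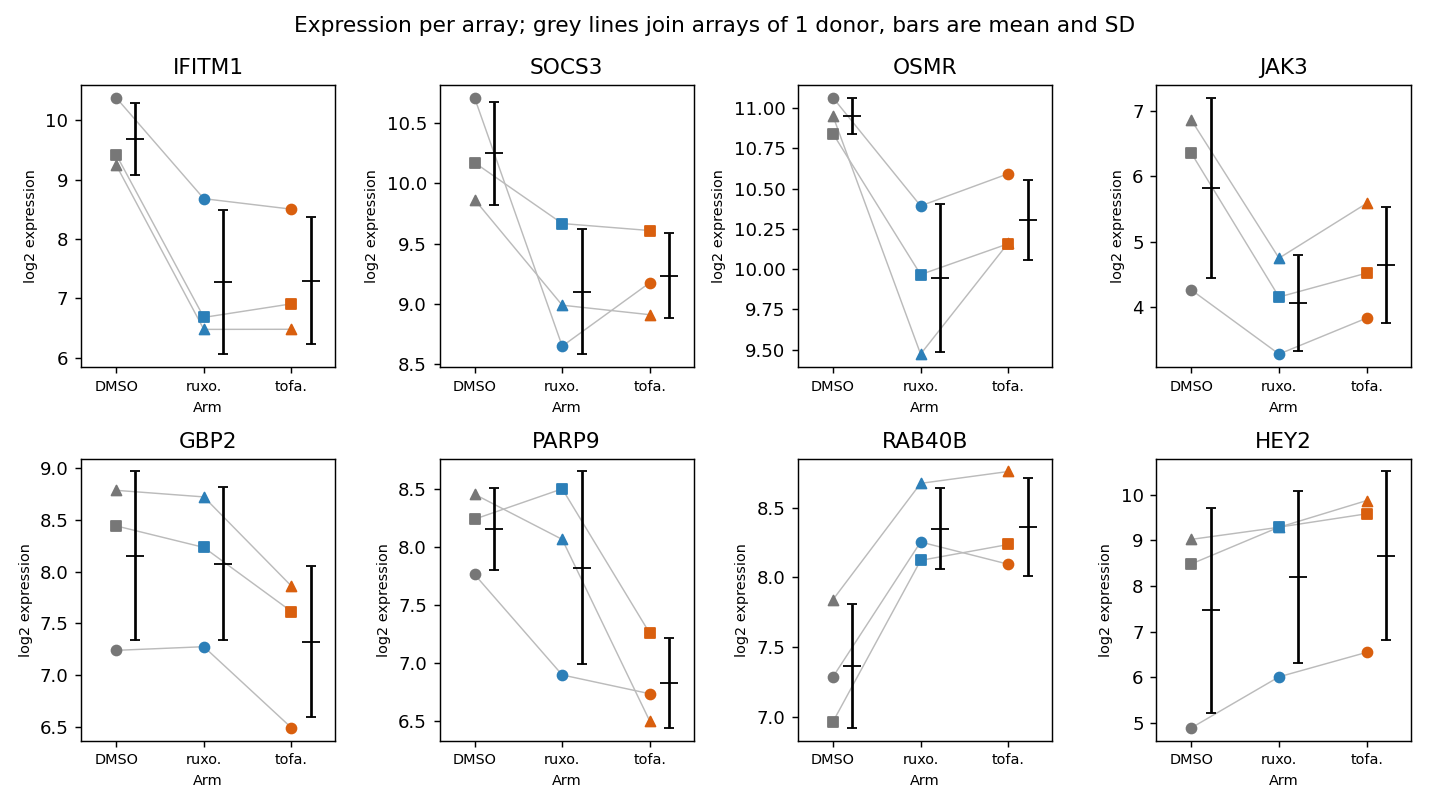
Log2 expression (y axis) of 8 genes by arm (x axis), 1 point per array with 1 marker shape per donor, grey lines joining the arrays of 1 donor, and bars at the mean ± SD of 3 arrays. IFITM1 lay at 9.68 ± 0.61 in DMSO against 7.28 ± 1.22 with ruxolitinib and 7.30 ± 1.07 with tofacitinib, while the other genes did not pass the threshold.

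Of the 36 type I interferon genes tested, 31 had a value below 0 with the drugs, and the list mean was -0.33 ± 0.08 (SE). The list passed camera's test with an adjusted p of 3.38e-08, against an adjusted p = 0.0901 with an estimated correlation. The 27 interferon gamma and antigen presentation genes fell as a group by -0.22 ± 0.10 on average (adjusted p = 0.000682, and adjusted p = 0.399 with an estimated correlation). The mean was -0.13 without tofacitinib replicate 3 and -0.34 ± 0.16 with the ACTB covariate. The members of this list with the smallest p were the complement protease gene C1R (-0.79 ± 0.15) and the interferon-induced GTPase gene GBP2 (-0.46 ± 0.12). GBP2 was at -0.84 with tofacitinib and -0.08 with ruxolitinib (-0.43 by its other probe set). With ruxolitinib alone the interferon gamma list missed the threshold (camera adjusted p = 0.13), with 14 members below 0 and 13 above. The 23 targets in STAT3 and STAT5 feedback fell as a group by -0.17 ± 0.07 (adjusted p = 0.00191, and adjusted p = 0.164 with an estimated correlation). Among them the oncostatin M receptor gene OSMR was at -0.83 ± 0.16 and SOCS3, a feedback inhibitor of JAK signalling, at -1.08 ± 0.24. With tofacitinib alone the feedback list missed the threshold (-0.07 ± 0.09, camera adjusted p = 0.0901). The 28 JAK-STAT components fell as a group by -0.14 ± 0.06 (adjusted p = 0.0115, and adjusted p = 0.164 with an estimated correlation). JAK3 was at -1.48 ± 0.24 and TYK2 at -0.42 ± 0.13, against 0.06 ± 0.15 for JAK1, -0.13 ± 0.26 for JAK2 (0.27 by its other probe set) and -0.27 ± 0.18 for STAT3 (-0.36 and 0.18 by its others). JAK3 was dim and near the level for testing of 4. Its arrays lay at 4.26 to 6.86 in DMSO, 3.28 to 4.75 with ruxolitinib and 3.83 to 5.59 with tofacitinib. IFITM1 was the 1 member of these lists past the threshold over all genes. Adjusted over the list alone, 1 type I interferon gene passed, 1 interferon gamma gene, 2 feedback targets and 2 JAK-STAT components. The lists overlap, with OSMR and STAT3 in both the feedback and the JAK-STAT list, so these counts may hold 1 gene more than once.

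Of the 21 cell cycle genes tested, 17 had a value below 0, and the list fell by -0.44 ± 0.09 on average (camera adjusted p = 2.6e-07, and adjusted p = 0.164 with an estimated correlation). The DNA topoisomerase gene TOP2A was at -0.89 ± 0.23 and BIRC5, which encodes survivin, at -0.98 ± 0.29. The 24 NF-kappaB inflammatory genes fell as a group by -0.30 ± 0.11 (adjusted p = 0.00191, and adjusted p = 0.382 with an estimated correlation), with the chemokine gene CXCL1 at -0.71 ± 0.20. The NF-kappaB mean was below 0 in 2 of 3 donors, -0.14 without DMSO replicate 3, where its call ended, -0.20 over members with a mean of at least 6 and -0.67 ± 0.12 with the ACTB covariate, and the other lists that passed moved the same way in 3 of 3. With tofacitinib alone the NF-kappaB list missed the threshold (-0.17 ± 0.13, camera adjusted p = 0.236). The hypoxia and glycolysis list fell by -0.10 ± 0.07 over 30 genes (adjusted p = 0.0214, and adjusted p = 0.382 with an estimated correlation). With ruxolitinib alone the hypoxia list missed the threshold (camera adjusted p = 0.0651). Of 19 p53 and senescence genes, 16 were above 0 and the list rose by 0.16 ± 0.07 (adjusted p = 0.0077, and adjusted p = 0.35 with an estimated correlation). SESN1, a p53 target, was at 0.42 ± 0.13, and CDKN2A, which encodes the cell cycle inhibitor p16, at 0.45 ± 0.17. With tofacitinib alone the p53 list missed the threshold (camera adjusted p = 0.0536). In these 4 lists 0 members passed over all genes and 0 adjusted over the list alone.

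Among genes that did not pass, those with the smallest p were RAB40B (0.99 ± 0.13, but 0.21 and 0.25 by its other probe sets), H2AC8, a histone gene (1.00 ± 0.13), OLFML2A (0.85 ± 0.12), RASL11B (1.06 ± 0.17) and the amino acid transporter gene SLC7A8 (0.77 ± 0.13) on the higher side. On the lower side they were MCAM, an adhesion molecule (-0.86 ± 0.13), ALPK2 (-0.80 ± 0.13) and CCBE1 (-1.28 ± 0.21). In the same arrays the signal of the 3' probe set of ACTB exceeded that of its 5' probe set by 2.66 ± 0.53 in DMSO, 2.35 ± 0.08 with ruxolitinib and 2.08 ± 0.22 with tofacitinib (SD, n = 3). This difference, which is larger where RNA is more degraded, was smaller in the drug arms than in DMSO, at -0.45 on average and in 3 of 3 donors (exact permutation p = 0.037, two-sided, the smallest that 27 choices allow). The same measure for GAPDH was at -0.12 (exact permutation p = 0.222). For ACTB the DMSO arrays lay at 2.30, 3.27 and 2.42 in donors 1, 2 and 3, so the gap was widest in donor 2. Without DMSO replicate 2, whose ACTB difference was highest (3.27), 0 genes and 8 lists passed for both drugs against DMSO, 0 genes and 8 lists for each drug alone, and 0 genes and 5 lists between the drugs. The IFITM1 call ended without the donor block (-2.40 ± 0.62, adjusted p = 1.00), with no filter on dim genes (-2.40, adjusted p = 0.155), with the ACTB covariate (-2.17 ± 0.33, adjusted p = 0.752) and in 11 of 12 fits that left out an array or donor, where the change was -2.70 to -2.21. Of 19 lists tested, 8 passed with camera's preset correlation, and 0 passed with an estimated correlation or with fry. In the 12 fits that left out an array or donor, the calls of the type I interferon, interferon gamma, feedback and cell cycle lists were lost in 0, NF-kappaB in 2, JAK-STAT components in 4, p53 in 5 and hypoxia in 7. A fit without a DMSO array had the same estimates as the fit without its donor, so these fits partly repeat each other. All 8 lists passed with the ACTB covariate, where sterol synthesis was gained, the feedback mean was -0.32 ± 0.10 and the hypoxia mean -0.16 ± 0.10. Of the 27 choices of 1 array per donor as control, a list mean as large came from 1, the real one, for the type I interferon, cell cycle, JAK-STAT and p53 lists. It came from 3 for hypoxia, 4 each for interferon gamma and feedback, and 6 for NF-kappaB (exact permutation adjusted p from 0.176 to 0.469 over 19 lists). As 27 choices allow no exact p below 0.037, an adjusted p under 0.05 over 19 lists was nearly out of reach.

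**Figure D2:**
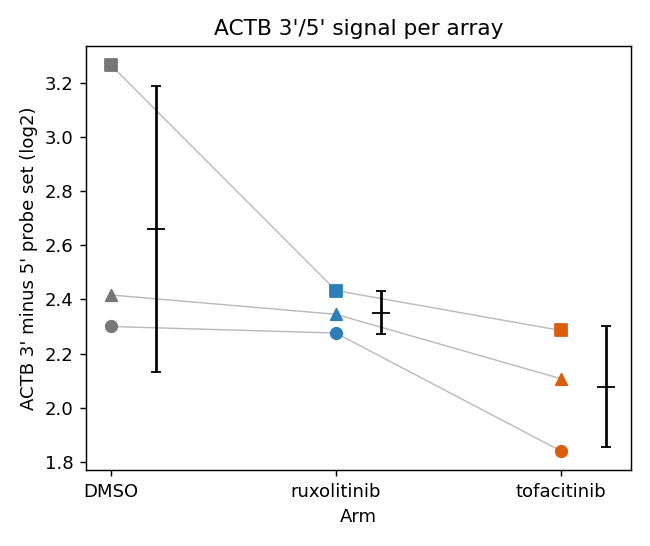
Difference between the 3' and the 5' probe set of ACTB in log2 (y axis) by arm (x axis), 1 point per array with 1 marker shape per donor, grey lines joining the arrays of 1 donor, and bars at the mean ± SD of 3 arrays. The means were 2.66 in DMSO, 2.35 with ruxolitinib and 2.08 with tofacitinib.

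Tofacitinib alone was compared with DMSO to describe the response to this drug. Type I interferon, interferon gamma, cell cycle, JAK-STAT component and hypoxia genes fell as groups at the preset correlation, and Notch pathway genes rose as a group. With an estimated correlation 0 of these 6 lists passed (adjusted p from 0.0788 to 0.4). For no single gene did the change pass: 0 of 10533 genes had an adjusted p under 0.05 (limma, smallest 0.11), and 539 had an unadjusted p under 0.05 where 527 are expected. IFITM1 was at -2.39 ± 0.23 (SE, n = 3 donors). The ACTB difference was 2.08 in these arrays against 2.66 in DMSO.

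The type I interferon list fell by -0.38 ± 0.09 on average, with 32 of 36 members below 0 (camera adjusted p = 8.15e-09, and adjusted p = 0.0788 with an estimated correlation). PARP9, a partner in interferon signalling, was at -1.32 ± 0.29. The interferon gamma list fell by -0.29 ± 0.11 with 23 of 27 members below 0 (adjusted p = 5.54e-06, and adjusted p = 0.4 with an estimated correlation), GBP2 being at -0.84 ± 0.14 and C1R at -0.81 ± 0.18. Its mean was -0.21, -0.05 and -0.61 in the 3 donors, and -0.11 without tofacitinib replicate 3. The cell cycle list fell by -0.41 ± 0.10 with 16 of 21 members below 0 (adjusted p = 1.35e-05, and adjusted p = 0.241 with an estimated correlation). CCNA2, which encodes cyclin A2, was at -0.74 ± 0.22. The mitotic kinase gene AURKA was at -1.36 ± 0.41 (-1.95 to -0.67 when an array or donor was left out), and at -0.70 by its other probe set. The JAK-STAT components fell by -0.14 ± 0.07 (adjusted p = 0.0324, and adjusted p = 0.241 with an estimated correlation), with the dim gene JAK3 at -1.18 ± 0.28 and TYK2 at -0.63 ± 0.15. The hypoxia list fell by -0.10 ± 0.08 with the interval of its mean reaching from -0.28 to 0.07 (adjusted p = 0.0454, and adjusted p = 0.4 with an estimated correlation), and was -0.05 without tofacitinib replicate 3. HK1, the hexokinase gene, was at -0.48 ± 0.18, and the glucose transporter gene SLC2A1 at 0.41 ± 0.17. The 11 Notch pathway genes rose by 0.23 ± 0.08 with 7 members above 0 (adjusted p = 0.0332, and adjusted p = 0.244 with an estimated correlation). The transcription factor gene HEY2 was at 1.20 ± 0.20, but its other probe set gave -0.01. Over all genes 0 members passed, and adjusted over the list alone 2 passed for each of the type I interferon, interferon gamma and JAK-STAT lists, 1 for Notch, and 0 for cell cycle and hypoxia.

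Other genes with the smallest p under tofacitinib were OLFML2A (0.98 ± 0.14), RAB40B (1.00 ± 0.15, but 0.18 and 0.25 by its other probe sets), H2AC8 (1.00 ± 0.15) and RASL11B (1.16 ± 0.20) on the higher side. On the lower side they were ALPK2 (-1.05 ± 0.15), CCBE1 (-1.36 ± 0.24) and the matrix protein gene EFEMP1 (-0.71 ± 0.13). Without replicate 1, 2 of the 6 lists passed. Over the 12 fits that left out an array or donor, the calls of the type I and interferon gamma lists were lost in 0, cell cycle in 2, JAK-STAT components in 5, Notch in 7 and hypoxia in 10. Fits without a ruxolitinib array kept the estimates of the main fit, so only their spread could move a call. Notch also missed the threshold without the donor block (adjusted p = 0.421), with donor as a random block (adjusted p = 0.322) and with no filter (adjusted p = 0.0544). A fit with the ACTB covariate passed 9 lists: Notch (0.19 ± 0.13, adjusted p = 0.226) and hypoxia (-0.18 ± 0.13, adjusted p = 0.0715) were lost. Gained were NF-kappaB (-0.65 ± 0.15, adjusted p = 0.000133, against -0.17 ± 0.13) and feedback (-0.27 ± 0.13, adjusted p = 0.0449, against -0.07 ± 0.09). Also gained were Wnt (-0.30 ± 0.12, adjusted p = 0.0391, against 0.01 ± 0.09), p53 (adjusted p = 0.0234) and sterol synthesis (-0.26 ± 0.12, adjusted p = 0.0255, against -0.05 ± 0.08). The type I interferon mean was then -0.58 ± 0.14 and that of interferon gamma -0.44 ± 0.20. IFITM1 passed for this drug alone when only genes with a mean of at least 6 were tested, with trended and robust variances, or without DMSO replicate 1, each of which gave 1 gene.

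**Figure D3:**
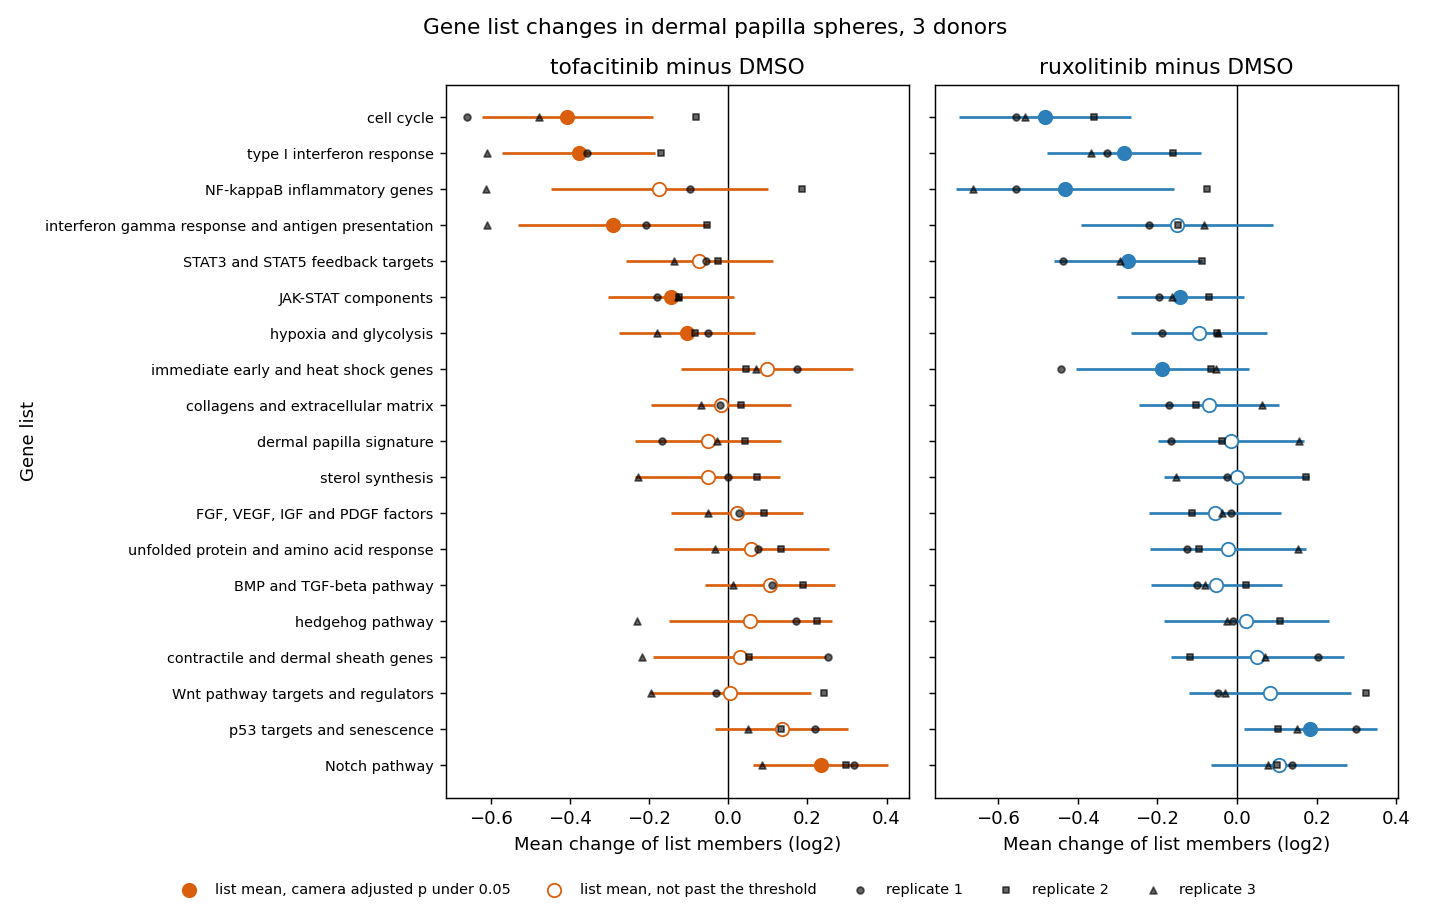
Mean log2 change of the tested members of each gene list (x axis) for 19 lists (y axis), tofacitinib minus DMSO on the left and ruxolitinib minus DMSO on the right. Large circles are list means with 95% intervals, filled where camera's adjusted p was under 0.05, and small symbols are the 3 donors. The type I interferon mean was -0.38 with tofacitinib and -0.28 with ruxolitinib.

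Ruxolitinib alone was compared with DMSO in the same way. Cell cycle, type I interferon, STAT3 and STAT5 feedback, NF-kappaB, JAK-STAT component and immediate early genes fell as groups at the preset correlation, and p53 and senescence genes rose as a group. With an estimated correlation 0 of these 7 lists passed (adjusted p from 0.162 to 0.441). Again 0 of 10533 genes passed singly (limma, smallest adjusted p = 0.104), and 506 had an unadjusted p under 0.05 where 527 are expected. IFITM1 was at -2.40 ± 0.23 (SE, n = 3 donors). The ACTB difference was 2.35 in these arrays against 2.66 in DMSO. By donor it was 2.28, 2.43 and 2.35 with ruxolitinib against 2.30, 3.27 and 2.42 in DMSO. The gap therefore lay mostly in donor 2.

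The cell cycle list fell by -0.48 ± 0.10, with 17 of 21 members below 0 (camera adjusted p = 6.84e-06, and adjusted p = 0.192 with an estimated correlation), BIRC5 being at -1.12 ± 0.33 and TOP2A at -0.89 ± 0.27. The type I interferon list fell by -0.28 ± 0.09 with 25 of 36 members below 0 (adjusted p = 6.2e-05, and adjusted p = 0.162 with an estimated correlation). IFITM2, of the same family as IFITM1, was at -0.51 ± 0.14. The STAT3 and STAT5 feedback list fell by -0.27 ± 0.09 with 21 of 23 members below 0 (adjusted p = 6.2e-05, and adjusted p = 0.162 with an estimated correlation). OSMR was at -1.01 ± 0.18 and SOCS3 at -1.15 ± 0.28. The NF-kappaB list fell by -0.43 ± 0.13 with 19 of 24 members below 0 (adjusted p = 6.2e-05, and adjusted p = 0.295 with an estimated correlation; -0.22 over members with a mean of at least 6), CXCL1 being at -1.18 ± 0.24 and the cytokine gene IL24 at -1.96 ± 0.43. The JAK-STAT components fell by -0.14 ± 0.07 (adjusted p = 0.0464, and adjusted p = 0.248 with an estimated correlation), with the dim gene JAK3 at -1.77 ± 0.28. Immediate early and heat shock genes fell by -0.19 ± 0.10 (adjusted p = 0.0464, and adjusted p = 0.441 with an estimated correlation). Their mean was -0.44, -0.07 and -0.05 in the 3 donors, and -0.04 without ruxolitinib replicate 1, where the call ended. The matricellular gene CCN1 was at -0.95 ± 0.26 and the nuclear receptor gene NR4A2 at 0.82 ± 0.32. The p53 and senescence list rose by 0.18 ± 0.08 with 16 of 19 members above 0 (adjusted p = 0.00961, and adjusted p = 0.295 with an estimated correlation). SESN1 was at 0.64 ± 0.16 and CDKN2A at 0.58 ± 0.20. Over all genes 0 members passed, and adjusted over the list alone 2 passed in each of the feedback, NF-kappaB and JAK-STAT lists, 1 in the type I interferon list, and 0 in the cell cycle, immediate early and p53 lists.

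Other genes with the smallest p under ruxolitinib were RAB40B (0.99 ± 0.15, but 0.18 and 0.32 by its other probe sets), H2AC8 (1.01 ± 0.15), SLC7A8 (0.81 ± 0.15) and MYLK-AS1, an antisense RNA gene (0.88 ± 0.16), on the higher side. On the lower side they were MCAM (-1.20 ± 0.15), the formin gene DIAPH3 (-1.36 ± 0.18) and MCUB, a regulator of mitochondrial calcium uptake (-1.27 ± 0.20). Without replicate 3, 3 of the 7 lists passed, and without DMSO replicate 3 also 3, the NF-kappaB mean then being -0.26. Over the 12 fits that left out an array or donor, the calls of the cell cycle, type I interferon and feedback lists were lost in 0, NF-kappaB in 2, p53 in 5, immediate early in 6 and JAK-STAT components in 7. Fits without a tofacitinib array kept the estimates of the main fit, so only their spread could move a call. JAK-STAT components also missed the threshold without the donor block (adjusted p = 0.1) and with genes of a mean of at least 6 (adjusted p = 0.0621), as did immediate early genes there (adjusted p = 0.104). The ACTB covariate gave 9 lists, the 7 with interferon gamma (-0.23 ± 0.14 against -0.15 ± 0.11, adjusted p = 0.0309) and hypoxia (adjusted p = 0.0396), and an NF-kappaB mean of -0.68 ± 0.11. IFITM1 passed for this drug alone under the same 3 settings as for tofacitinib.

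Tofacitinib was compared with ruxolitinib at the same dose and time. At the preset correlation, immediate early and heat shock genes were higher with tofacitinib as a group, as were NF-kappaB, STAT3 and STAT5 feedback, BMP and TGF-beta, and Notch genes. Interferon gamma genes were lower with tofacitinib as a group, though their mean was below 0 in 1 of 3 donors. With an estimated correlation 0 of these 6 lists passed (adjusted p from 0.377 to 0.675), and with the ACTB covariate 1 did, interferon gamma. The IFITM1 level did not separate the drugs: the difference was 0.02, with a 95% interval from -0.52 to 0.55. For single genes 0 of 10533 passed (limma, smallest adjusted p = 0.945), and 463 had an unadjusted p under 0.05 where 527 are expected. The ACTB difference was 2.08 with tofacitinib and 2.35 with ruxolitinib.

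The mean of 25 immediate early and heat shock genes was higher with tofacitinib by 0.28 ± 0.10 (camera adjusted p = 0.00367, and adjusted p = 0.377 with an estimated correlation). CCN1 differed by 0.85 ± 0.26 and MYC by 0.83 ± 0.28. The list mean was 0.12 without replicate 1, where the call ended. The NF-kappaB list was higher by 0.26 ± 0.13 (adjusted p = 0.018, and adjusted p = 0.647 with an estimated correlation), with the chemokine gene CXCL8 at 0.97 ± 0.23 and CXCL1 at 0.95 ± 0.24. This list was at 0.04 ± 0.11 with the ACTB covariate (adjusted p = 0.755), over members with a mean of at least 6 at 0.05 (adjusted p = 0.344), and without the donor block it missed the threshold (adjusted p = 0.0635). It ran from 0.16 (without replicate 1) to 0.42 (without tofacitinib replicate 3). The feedback list was higher by 0.20 ± 0.09 (adjusted p = 0.0357, and adjusted p = 0.378 with an estimated correlation), with the kinase gene PIM1 at 0.98 ± 0.29. The feedback mean was 0.11 without replicate 1 and 0.11 ± 0.09 with the ACTB covariate (adjusted p = 0.196). The BMP and TGF-beta list was higher by 0.16 ± 0.08 (adjusted p = 0.0357, and adjusted p = 0.377 with an estimated correlation), with BMP2 at 1.36 ± 0.54 (0.61 without ruxolitinib replicate 1). It missed the threshold with genes of a mean of at least 6 (adjusted p = 0.0602). The Notch list was higher by 0.13 ± 0.08 (adjusted p = 0.0407, and adjusted p = 0.377 with an estimated correlation), with NOTCH1 at 0.46 ± 0.15. The Notch mean ran from 0.09 (without replicate 2) to 0.20 (without tofacitinib replicate 3). This list missed the threshold without the donor block (adjusted p = 0.158), with donor as a random block (adjusted p = 0.11) and with no filter (adjusted p = 0.0565), as did the feedback list with no filter (adjusted p = 0.0648). The interferon gamma list was lower, at -0.14 ± 0.11 (adjusted p = 0.00903, and adjusted p = 0.675 with an estimated correlation), with GBP2 at -0.76 ± 0.14 (-0.35 by its other probe set), and the list mean was -0.21 ± 0.13 with the ACTB covariate. Over all genes 0 members passed, and adjusted over the list alone 1 interferon gamma gene passed and 0 in the other 5 lists. For the type I interferon list the difference was -0.09, with a 95% interval from -0.29 to 0.10, and for the cell cycle list 0.08, from -0.14 to 0.29.

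Single genes with the smallest p were MAP7 (1.08 ± 0.18), USP31 (0.97 ± 0.17) and the receptor kinase gene ROR1 (0.77 ± 0.15), with values higher under tofacitinib. The other probe sets of USP31 ran from -0.32 to 0.40, 2 of 3 with opposite sign, and that of ROR1 gave -0.15. NUDT7 (-1.23 ± 0.19), HSPA4L (-1.18 ± 0.22), MBNL3 (-0.97 ± 0.18) and RSRP1 (-1.11 ± 0.22) had lower values. Without replicate 1, 0 of the 6 lists passed, and without replicate 3 the interferon gamma mean was 0.05. Over the 12 fits that left out an array or donor, the calls were lost in 3 for immediate early, 5 for interferon gamma, 6 for NF-kappaB and for feedback, 9 for BMP and TGF-beta and 10 for Notch. Fits without a DMSO array kept the estimates of the main fit, so only their spread could move a call.

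The changes under the 2 drugs correlated across genes at r = 0.536, and 68.5% of genes had the same sign; genes are not independent replicates. Unchanged arms simulated against shared controls gave r = 0.500 on average and at most 0.528 in 100 simulations. The covariance was 0.0398, against 0.0266 simulated and at most 0.0288. The 3 controls could not be split into parts of 2, so part of the excess may come from the shared arrays. The simulated noise was independent between genes, so its narrow spread cannot show how far r varies by chance. In the 3 donors taken singly r was 0.519, 0.635 and 0.303. No shared effect of the drugs is therefore concluded from the excess. Of the lists that fell, 5 did so with tofacitinib and 6 with ruxolitinib, 3 of them shared. Of the lists that rose, 1 did so with each drug and 0 were shared. Of 100 assignments of the arms within donors, each with both drugs set against the same 3 arrays, 10 gave at least 3 shared lists, the real one included. The others gave 0.65 on average and at most 4.

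The dermal papilla signature did not pass for either drug. Its mean change was -0.05 with tofacitinib (95% interval -0.24 to 0.13) and -0.02 with ruxolitinib (-0.20 to 0.17). VCAN was at -0.12 ± 0.14 and -0.07 ± 0.14, and LEF1 at 0.93 ± 0.29 and 0.45 ± 0.29, respectively, the last being 0.10 to 0.83 when an array or donor was left out. Wnt, hedgehog, growth factor, collagen, contractile, sterol and unfolded protein lists also missed the threshold in every comparison of the main fit. The Wnt list passed with the ACTB covariate for tofacitinib, as did the sterol list for tofacitinib and for both drugs (-0.18 ± 0.10, adjusted p = 0.0351), while the Wnt mean for both drugs was -0.19 ± 0.10 (adjusted p = 0.114). For both drugs against DMSO the means in the main fit were 0.04 ± 0.08 for Wnt, 0.04 ± 0.08 for hedgehog, -0.02 ± 0.07 for growth factors and -0.04 ± 0.07 for collagens. They were 0.04 ± 0.09 for contractile genes, -0.03 ± 0.07 for sterol synthesis and 0.02 ± 0.08 for the unfolded protein response. The medians of the Wnt and hedgehog lists, -0.02 each, differed in sign from their means.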

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

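The lists below were fixed before the data were examined. The fit with the ACTB covariate was chosen only after the list results were seen.

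A test of the difference between the drugs singled out 6 lists at camera's preset correlation, given as tofacitinib minus ruxolitinib. With an estimated correlation 0 of them passed (adjusted p from 0.377 to 0.675), and with the ACTB covariate 1 did, interferon gamma. The mean differences were -0.14 for interferon gamma and antigen presentation, 0.20 for STAT3 and STAT5 feedback, 0.16 for BMP and TGF-beta, 0.13 for Notch, 0.26 for NF-kappaB and 0.28 for immediate early and heat shock genes. In 10 splits of these 6 arrays the real one gave 6 lists and the next 3, and 10 splits are too few for a share under 0.05.

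The higher immediate early list with tofacitinib was weighed further. Without replicate 1 the difference was 0.12 and missed the threshold (adjusted p = 0.337), against 0.37 without replicate 2 and 0.36 without replicate 3. It may therefore rest mostly on 1 donor, in which it was 0.62 against 0.11 and 0.12 in the others. With the ACTB covariate the difference went from 0.28 ± 0.10 to 0.22 ± 0.12 (SE), smaller and less precise, and its call ended (adjusted p = 0.0603). An effect of RNA 3' bias therefore cannot be told apart from a difference between the drugs. A biological difference between the inhibitors stays open and untested beyond this.

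Among 2850 probe sets outside the gene table, 1 passed for both drugs against DMSO, with a change of -2.03 ± 0.15 (SE, limma adjusted p = 0.0281). Its level was 10.54 in DMSO, 8.44 with ruxolitinib and 8.58 with tofacitinib. It is annotated to 2 genes and is therefore not named.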

How the results depend on the processing

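The fit with the ACTB covariate, the list without IFITM1 and the alternatives for the variance share were chosen after the data were seen; the rest were planned. For both drugs against DMSO the count was 1 gene. It was 0 with no donor block, with donor as a random block, with no filter, over every probe set and with the covariate, and 0 to 1 over the fits leaving out an array or donor (1 without DMSO replicate 1). The IFITM1 change ranged from -2.70 to -2.17 over 22 alternatives, with adjusted p from 0.00233 to 1.00, and 7 of them passed. For each drug alone the count of 0 became 1 at a mean of at least 6 and with trended and robust variances, and was 0 to 1 over the leave-out fits. The drugs against each other gave 0 throughout. The donor block changed no call of a single gene other than IFITM1. Of 27 list calls, 4 were lost without it, 7 with the mean of all probe sets, 7 with the ACTB covariate and 5 with array weights. With an estimated correlation or fry, 0 lists passed in each comparison. Over leave-out fits the lists passing were 2 to 8 for tofacitinib (6 with all arrays), 3 to 8 for ruxolitinib (7), 5 to 8 for both drugs (8) and 0 to 6 between the drugs (6). Counts moved by over 1.5 times for tofacitinib without replicate 1 or tofacitinib replicate 1 (2 lists), and without DMSO replicate 1 or tofacitinib replicate 2 (3). For ruxolitinib they did so without replicate 3 or DMSO replicate 3 (3), and without replicate 1, DMSO replicate 1 or ruxolitinib replicate 1 (4). For both drugs this held without replicate 1, replicate 3, DMSO replicate 1 or DMSO replicate 3 (5). Between the drugs it held without replicate 1 or tofacitinib replicate 1 (0), ruxolitinib replicate 1 (1), tofacitinib replicate 2 (3), and replicate 3 or either of its drug arrays (2). Between the drugs, array weights, whose estimation stopped before it converged, gave 2 lists and the ACTB covariate 1. The interferon gamma mean between the drugs ran from -0.258 to 0.0531 over these fits, being 0.0531 without replicate 3 and 0.0362 without tofacitinib replicate 3. The type I interferon list passed in all 12 leave-out fits for each drug and for both. These fits are not all separate checks, as those without an array of the other drug kept the main estimates for a single drug. The correlation of the drugs' changes ran from 0.363 (without ruxolitinib replicate 2) to 0.680, against 0.536. Of 198 values of named genes, 85 moved by over 1.5 times and 20 changed sign when an array or donor was left out. The variance share of treatment was 11.4% with no filter, against 10.2%. The cause of these changes was not tested, except that fits with fewer arrays or more genes have less power by construction. Dim genes, 9207 below the level for testing, set the limit of what was measured.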

Other observations

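The patterns weighed here were chosen after the list results were seen, and the fit with the ACTB covariate and the list without IFITM1 were chosen only then.

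Some growth regulators of hair follicle mesenchyme had values that did not pass. The angiogenic factor gene VEGFA was at -0.46 ± 0.16 with ruxolitinib and -0.25 ± 0.16 with tofacitinib (SE, n = 3 donors), or -0.54 to -0.33 and -0.38 to -0.15 when an array or donor was left out. Its 3 other probe sets ran from -0.45 to -0.21 with ruxolitinib and from -0.36 to 0.02 with tofacitinib. HGF was at 1.09 ± 0.46 with ruxolitinib (0.40 to 1.84 when an array or donor was left out), and FGF5, a factor known to end hair growth, at 0.37 ± 0.16 with tofacitinib (0.23 to 0.47). The Wnt target AXIN2 was at 0.49 ± 0.27 with tofacitinib (0.21 to 0.87) and the Wnt receptor gene FZD2 at 0.69 ± 0.28 with ruxolitinib (0.29 to 0.97, and 0.07 by its other probe set).

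The type I interferon list was lower in the drug arms by -0.33. With the ACTB covariate it was at -0.49 ± 0.11 (SE), so adjusting for the ACTB difference did not weaken it. That difference was itself lower in the drug arms in 3 of 3 donors and covers only ACTB, so RNA 3' bias is not excluded. Leaving out each donor in turn weakened the list mean at most to -0.25 (without replicate 3). Without IFITM1 the list still passed camera (adjusted p = 5.07e-07). Of 27 choices of 1 control array per donor, 1 gave a change as large, the real one, against 0.25 for the next. Over 19 lists the exact test's adjusted p is 0.176, but 27 choices allow no exact p below 0.037. An adjusted p under 0.05 was thus nearly out of reach, and the test decides neither way. Of the 8 lists that passed for both drugs, 4 had other choices as large. A hypothesis is that both inhibitors may have lowered basal interferon signalling. It stays open, as the list missed the threshold with an estimated correlation (camera adjusted p = 0.0901). The estimated correlation was 0.0148 against the preset 0.01, so a larger correlation between its genes alone does not account for that loss. JAK-STAT components (both drugs) and Notch (tofacitinib) also lost their calls, at estimated correlations of -0.00656 and -0.044, below the preset. A larger correlation therefore cannot account for those losses. The hypothesis was not tested by a measure of interferon in the medium.

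The cell cycle list was lower by -0.44. Leaving out each donor weakened it at most to -0.36 (without replicate 1), so 1 donor is not the whole cause. With the ACTB covariate it was at -0.59 ± 0.13 (SE), so adjusting for the ACTB difference did not weaken it. That cannot exclude RNA 3' bias, since the ACTB difference was itself lower in the drug arms in 3 of 3 donors. Of 27 choices within donors, 1 was as large, the real one, against 0.40 for the next. Over 19 lists the exact test's adjusted p is 0.176, a value limited by the 27 choices, so it decides neither way. The list missed the threshold with an estimated correlation (camera adjusted p = 0.164). A hypothesis is that JAK inhibition may have slowed proliferation in the spheres, which was not tested by a count of cells.

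Other splits of the arrays were refitted. For genes, 10 of 10 splits gave as many as the real 0 for tofacitinib and for ruxolitinib against DMSO, with 0 the highest other count, and likewise 10 of 10 between the drugs, where another split gave 1. For lists, 1 of 10 splits reached the real 6 for tofacitinib (next 4) and 1 of 10 the real 7 for ruxolitinib (next 6). These 10 splits are too few for a share under 0.05. The splits for both drugs were fitted as control against the rest, not as 3 arms. With the donor block, 81 of the splits into 3 and 6 arrays could be fitted. Of these, 3 gave at least the real 1 gene, the highest other being 1, and 4 gave at least the real 8 lists, the highest other being 8. Both shares are under 0.05 among all splits, most of which do not keep the donor design. Of the 27 splits that keep 1 control per donor, 1 gave as many genes, with 0 the highest other, and 2 gave as many lists, with 8 the highest other. For the gene the share is under 0.05 in both sets, but 1 of 27 is the smallest share the design allows and no adjustment was made over the 4 comparisons. Chance is therefore not excluded for the gene, whose call also ended in 11 of 12 fits that left out an array or donor. For lists the share within donors is above 0.05, so chance is not excluded for them.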
